A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

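Ribosome profiling sequences the mRNA fragments that ribosomes protect from nuclease, so that the count on a coding sequence reflects the ribosomes found on it. The series compared 2 yeast strains in the 74D-694 background with 2 libraries each: a wild type (WT), and a strain, called mutant here, whose OAZ1 gene was exchanged for a version that is read without a change of frame. Per the labels' protocols, cells were grown to mid-exponential phase in synthetic medium, cycloheximide was added at 50 µg/mL to hold ribosomes in place, cells were broken with glass beads, and libraries were made with a TruSeq Small RNA kit. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No RNA-seq libraries were analysed here, so a change in ribosome count cannot be separated from a change in mRNA level.

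The authors deposited 1 table of whole-number counts per coding sequence, not normalized, with 1 column per library. The submitters' processing notes name Bowtie2, DESeq2 and sacCer3. Versions, the counting tool, the read-length filter, the strand setting, the treatment of reads with several matches and the annotation are not given in the sources used here. The table had 6600 rows, of which 746 had no count in any library. Row names were matched to the RefSeq annotation of the reference genome by systematic name: 5917 matched, and the 683 others held 0.0148% to 0.0206% of a library's counts. Columns were matched to samples by the strain and replicate in their names. The header line had single tabs and the other lines doubled tabs, so the names were assigned in order to the filled fields of each line, and the library of every value rests on that reading. Every row named a coding sequence.

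Total counts were 29671498 and 10202557 in WT replicates 1 and 2, and 7571371 and 2826895 in mutant replicates 1 and 2, a 10.5-fold range. A count of 0 allows up to 3 counts, or 0.101 CPM (counts scaled to a common library total of 1e6) in the deepest library and 1.06 CPM in the shallowest. Intervals on shares are 95% Wilson intervals. These intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

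Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided), with TMM normalization, the filterByExpr filter (minimum count 10, minimum total count 15) and Benjamini-Hochberg adjustment at 0.05 over the 5233 genes kept. CPM values are TMM-normalized, except those of OAZ1 with Wilson intervals, of mating type markers, and of genes given in the closing section, which are plain shares of the total. Before the data were examined, 37 gene lists were fixed. The 34 lists with at least 4 measured genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, again with Benjamini-Hochberg adjustment. A list's median is the median over its genes of the log2 difference on that scale, mutant minus WT, while single genes and counts of genes above or below 0 use the edgeR fold change. Camera was repeated with a correlation estimated per list, and fry was run as a test of whether a list's genes move, on balance, 1 way.

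The genes named were also fixed by rule before the data were examined. They were OAZ1 and the measured members of the lists for antizyme, polyamine synthesis, eIF5A and hypusination, auxotrophic markers and programmed frameshift genes. To these were added up to 12 genes per direction past the adjusted threshold with a mean count of at least 50 and no overlap of the groups, and up to 4 members of every other list with the smallest adjusted p. Genes outside the rule were chosen after their values were seen.

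Coding sequences were translated from the reference genome. A protein was said to have a hydrophobic segment where the mean Kyte-Doolittle hydropathy of any 19-residue window reached 1.6. This marks candidates for membrane or secreted proteins and misassigns some. Shared sequence between genes was measured as the share of a coding sequence's 28-mers present in another coding sequence. These values were available for 99.6% of the tested genes. Values were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots with matplotlib 3.10.9.

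The gene test was checked on simulated counts drawn from the means and library sizes of these libraries, with 200 changed genes in each of 5 draws over 5233 genes. It recovered 9.91% of genes changed 1.5-fold, 43.5% of genes changed 2-fold and 96% of genes changed 4-fold, and called 77 of 25074 unchanged genes. When WT replicate 1 was simulated with its own profile, a check chosen after the data were seen, over 5222 genes, it recovered 0%, 2.39% and 64.7% of genes at those folds and called 0 of 25057 unchanged genes. For lists of 60 genes, camera found 20 of 20 lists shifted by 0.25 on the log2 scale and called 3 of 400 unchanged lists of independent genes.

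The alternatives were RLE and upper-quartile scaling, 2 other filters, a replicate block, leaving out each library, robust dispersion estimates, leaving out mitochondrially encoded or ribosomal protein genes, a minimum fold of 1.2, DESeq2 1.42.0 and limma-voom. After the data were seen, limma-voom with sample quality weights, genes with no hydrophobic segment only, libraries thinned to the smallest total, and camera with an estimated correlation without either WT library were added. A result past the threshold under neither of 2 settings was treated as having no direction.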

Results

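The study compared ribosome-protected fragments between a WT yeast strain and a mutant in which OAZ1, the gene for ornithine decarboxylase antizyme, was exchanged for an in-frame version. Antizyme binds ornithine decarboxylase, the first enzyme of polyamine synthesis, and directs it to the proteasome. Its natural mRNA is read in full only when ribosomes change frame, which polyamines stimulate. The background, 74D-694, is a laboratory strain of Saccharomyces cerevisiae used in work on prions and translation termination. Each group had 2 libraries, with 29671498 and 10202557 counts in WT and 7571371 and 2826895 counts in mutant.

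OAZ1 (YPL052W) had a higher share of counts in both mutant libraries than in either WT library, but the difference did not pass the test over all genes. The counts were 379 and 110 in WT replicates 1 and 2 and 160 and 49 in mutant replicates 1 and 2. These correspond to 12.8 CPM (95% Wilson interval 11.6 to 14.1), 10.8 CPM (8.95 to 12.99), 21.1 CPM (18.1 to 24.7) and 17.3 CPM (13.1 to 22.9). After TMM normalization OAZ1 stood at 11.7 ± 1.39 CPM in WT and 19.3 ± 1.70 CPM in mutant (SD, n = 2 each). Its log2 fold change was 0.73 (SE 0.22), with an adjusted p of 0.755 in edgeR's quasi-likelihood test. The log2 fold change was 0.87 (adjusted p = 0.0769, edgeR) without WT replicate 1 and 0.63 (adjusted p = 0.0319, edgeR) without WT replicate 2. With all libraries thinned at random to the smallest total it was 0.36 (adjusted p = 0.791, edgeR) in the draw used, which kept 93 WT counts where 66.6 were expected. Over 20 further draws the median was 0.69 (0.31 to 1.00), none past the threshold.

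**Figure D1:**
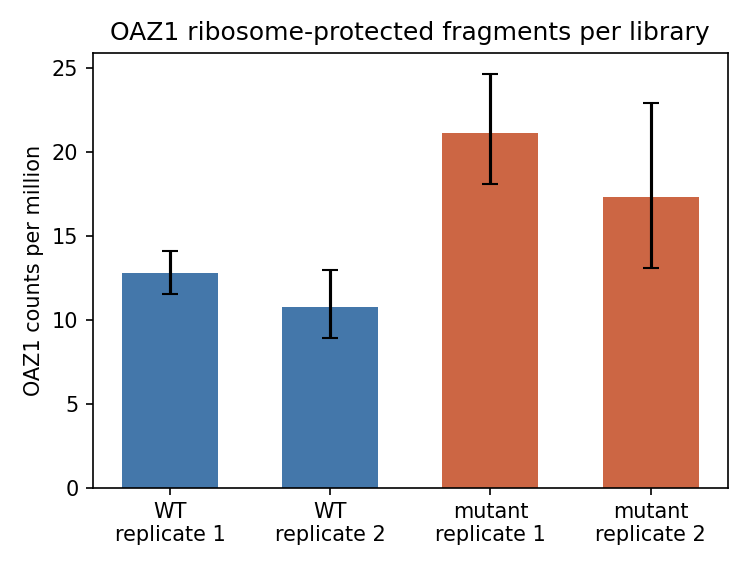
CPM of OAZ1 (vertical axis) in each library (horizontal axis), WT in blue and mutant in orange, with 95% Wilson intervals as error bars. The mutant libraries sit at 21.1 and 17.3 and the WT libraries at 12.8 and 10.8.

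In the reference annotation OAZ1 lies on the plus strand of chromosome XVI, from 458799 to 459678. Its coding sequence is given in 2 parts, 69 codons from 458799 to 459005 and 224 codons from 459007 to 459678, and the base at 459006 between them is skipped when the frame changes. The reference sequence around this point, from 458991 to 459021, is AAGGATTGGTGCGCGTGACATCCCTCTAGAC. The counts are totals per coding sequence, so ribosomes before and after the skipped base were not separated.

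WT replicate 1 stood apart from the other libraries, and from its own group. Over 4603 genes with a mean count of at least 100, the SD of the log2 difference was 0.509 between the WT libraries and 0.297 between the mutant libraries. It was 0.223 between WT replicate 2 and mutant replicate 1, less than within either group. These SDs are at unequal depth, and pairs with mutant replicate 2, the shallowest library, carry the most counting noise. Among genes with no hydrophobic segment, the SD between WT replicate 2 and mutant replicate 1 rose from 0.217 to 0.272 after thinning to the smallest total. Genes for proteins with a hydrophobic segment held 20.7% of the counts in WT replicate 1, against 16.6% in WT replicate 2 and 17.2% and 16.9% in mutant replicates 1 and 2. KAR2, the chaperone of the endoplasmic reticulum lumen, had 1414 CPM in WT replicate 1 and 560 CPM in WT replicate 2, with 455 and 479 CPM in mutant. HSP30, a plasma membrane stress protein, had 924 CPM in WT replicate 1 and 177 to 191 CPM in the other libraries. Cytosolic ribosomal protein genes held 14.2% and 14.8% of counts in WT and 16.1% and 17.9% in mutant. The 10 most abundant genes, led by PDC1 and ENO2, which were chosen after their values were seen, held 17.7% to 20.4%. No pair of libraries agreed within sampling noise, the chi-square per degree of freedom being at least 9.17.

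**Figure D2:**
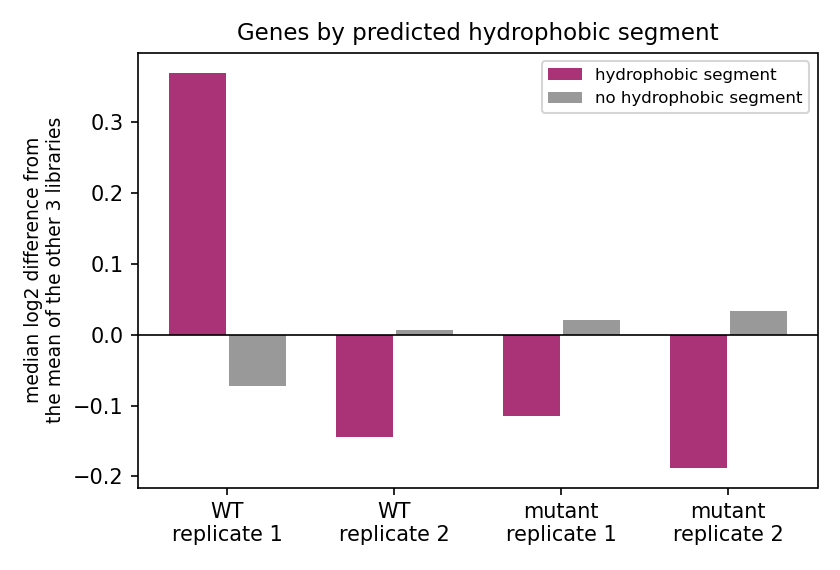
Median log2 difference of each library from the mean of the other 3 (vertical axis) for 1506 genes whose protein has a hydrophobic segment (purple) and 3704 genes without one (grey), by library (horizontal axis); bars start at 0 and carry no error. The medians for genes with a segment are 0.37 in WT replicate 1 and -0.14, -0.12 and -0.19 in WT replicate 2 and mutant replicates 1 and 2. For the libraries below 0 the mean of the other 3 includes WT replicate 1, so their medians do not show a depletion of their own.

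Across 5233 genes, none passed the adjusted threshold in edgeR's quasi-likelihood test, in either direction. The smallest adjusted p was 0.755. At an unadjusted p under 0.05 there were 285 genes, 90 higher and 195 lower in mutant. DESeq2 called 0 higher and 4 lower. These were PGM2, a phosphoglucomutase (log2 fold change -1.59, DESeq2 adjusted p = 0.000334), and FLO1, a flocculation protein (-2.23), ADH1 (-1.52) and ADH2 (-1.17), each at a DESeq2 adjusted p of 0.034. ADH1 and ADH2 encode alcohol dehydrogenases. FLO1 was chosen after its values were seen. The groups did not overlap for 1933 genes, 36.9% of those tested, where chance gives 33.3%.

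Leaving out 1 WT library changed these counts. Without WT replicate 1 edgeR called 17 genes higher and 22 lower, and without WT replicate 2 it called 228 higher and 780 lower, of which 587 encode proteins with a hydrophobic segment. In these fits the remaining WT library was assumed to vary like the mutant pair. Without either mutant library no gene was called. A simulation with no strain effect, chosen after the data were seen, in which WT replicate 1 kept its own profile, called a median of 1203 genes without WT replicate 2 over 20 draws, so those calls do not separate strain from library. Both WT leave-outs called 24 genes in common, 10 higher and 14 lower. At the same threshold that simulation called at most 1 gene without WT replicate 1 and at most 1 in both fits, and one with the same means in all libraries called 0 and 0. Taking as many top-ranked genes as the real fits called, the 2 simulations shared 5 to 14 and 13 to 23 genes between the fits. Both fits use the same mutant libraries, so they overlap without a strain effect, and the second range ends just below the real overlap. The correlation between the 2 fits was 0.339 in the real data, against medians of 0.182 and 0.441 in the simulations. The size of the overlap alone therefore does not separate strain from library. The simulations took their spread from the fit without WT replicate 1, so a displacement of WT replicate 2 or of both mutant libraries was not covered. Among the genes the rule named, this set had PGM2, ADH1, ADH2, TDH1, GSC2 and GCV1 lower and COX7, SAM4, TEF1 and LEU2 higher. PGM2 had 246 ± 66.5 CPM in WT and 81.4 ± 18.3 CPM in mutant (SD, n = 2 each). COX7, a subunit of cytochrome c oxidase, had 13.6 ± 0.24 CPM in WT and 27.3 ± 1.63 CPM in mutant (SD, n = 2 each). GSC2, a glucan synthase, had 80.6 ± 50.1 CPM in WT, from 116 and 45.2 CPM in replicates 1 and 2, and 25.1 ± 1.51 CPM in mutant. Its log2 fold change was -1.68 with all libraries and -0.84 without WT replicate 1. TEF1 is uncertain, since 95.9% of its 28-mers occur in another gene. That share was 28.8% for TDH1, 24.2% for SAM4 and 19.5% for ADH1 and for ADH2. The treatment of reads with several matches is not given, so these values carry the same doubt to a smaller degree.

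None of the genes of polyamine synthesis passed the test. SPE1, ornithine decarboxylase itself, had 131 ± 6.02 CPM in WT and 139 ± 16.5 CPM in mutant (SD, n = 2 each), a log2 fold change of 0.08 with a 95% interval from -0.34 to 0.49. The log2 fold changes were 0.11 for SPE2, 0.08 for SPE3, -0.17 for SPE4 and -0.13 for FMS1, a polyamine oxidase. The list of 5 genes had a median of 0.07 and a camera adjusted p of 0.951. The 4 genes of eIF5A and its hypusine modification, which takes its aminobutyl group from spermidine, were all above 0. Their log2 fold changes were 0.15 for HYP2, 0.67 for ANB1, 0.12 for DYS1 and 0.28 for LIA1, with a camera adjusted p of 0.0583. ANB1 had only 15 to 67 counts per library and fell to 0.27 without WT replicate 1, and DYS1 fell to 0.04 without mutant replicate 2. The share of sequence found in another gene was 8.72% for ANB1 and for HYP2, and HYP2 had 17853 to 165169 counts per library. The treatment of reads with several matches is not given, so the value of ANB1 is uncertain and may not be independent of other genes. Methionine salvage, which recycles a by-product of polyamine synthesis, had a median of 0.19 over 9 genes and a camera adjusted p of 0.0607. Of the other genes with programmed frameshifts, EST3 had a log2 fold change of 0.12 and ABP140 of -0.83, neither past the threshold with all libraries. ABP140 had 268 and 170 CPM in WT and 178 and 65.1 CPM in mutant. Its log2 fold change was -0.44 without WT replicate 1, -1.10 without WT replicate 2, -1.74 without mutant replicate 1 and -0.30 without mutant replicate 2. The value thus rested largely on mutant replicate 2 and in part on WT replicate 1.

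Camera placed 11 of the 34 lists past the threshold, 5 higher and 6 lower in mutant. With an estimated correlation 0 of the 34 lists passed, the smallest adjusted p being 0.817, and by fry 0 passed, the smallest adjusted p being 0.769. Camera with an estimated correlation has little power with 4 libraries, its smallest unadjusted p over the lists being 0.124. Neither test was checked on simulated lists, so the lack of calls does not show that the lists were unchanged. In none of the lists did a member pass the test over all genes. Adjusted over the list alone, 1 gene passed in the general stress list. OAZ1 was the single member of its own list, so no adjustment applied there and its p stayed at the unadjusted 0.017 (edgeR).

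**Figure D3:**
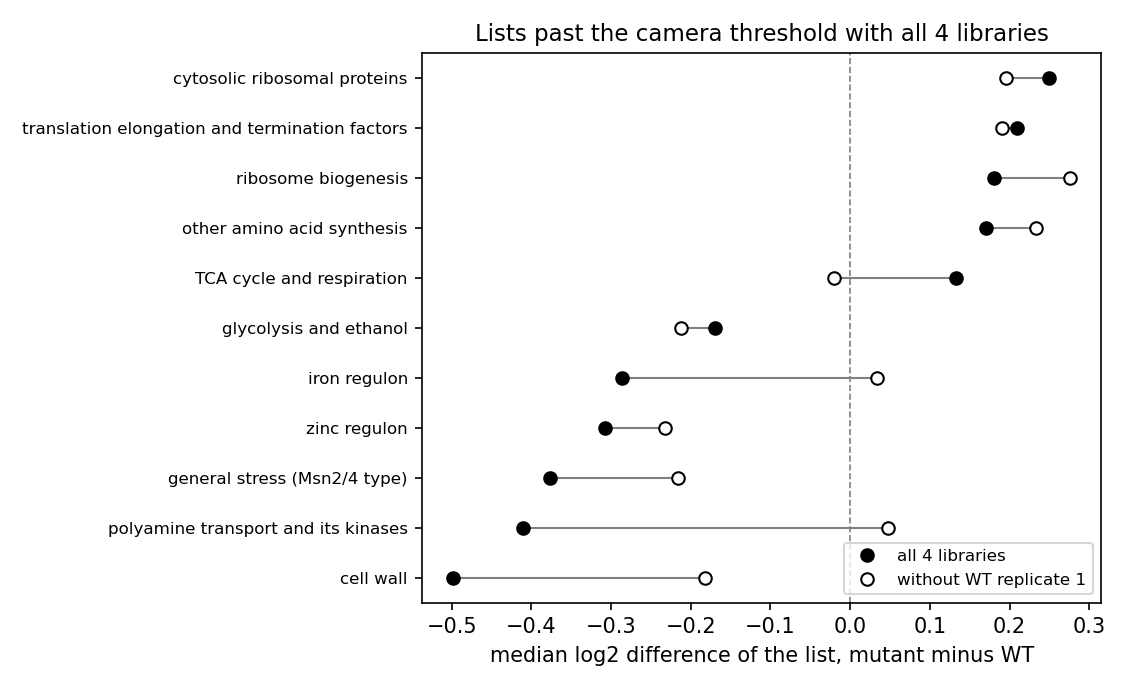
Median log2 difference, mutant minus WT (horizontal axis), of the 11 lists past the camera threshold (vertical axis), with all 4 libraries (filled) and without WT replicate 1 (open). The median of polyamine transport moves from -0.41 to 0.05 and that of cytosolic ribosomal proteins from 0.25 to 0.20.

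Genes of the translation machinery were higher in mutant as groups. Of 137 cytosolic ribosomal protein genes 126 lay above 0, with a median of 0.25 (camera adjusted p = 2.73e-14; adjusted p = 0.817 with an estimated correlation) and a median of 0.20 without WT replicate 1. Examples were RPL20B with a log2 fold change of 0.58, RPL11B with 0.57 and RPL37B with 0.53, none past the gene threshold; 20.3%, 67.5% and 12.9% of their 28-mers occur in another gene. Ribosome biogenesis had 51 of 61 genes above 0 and a median of 0.18 (camera adjusted p = 2.11e-06; adjusted p = 0.817 with an estimated correlation), among them KRR1 (0.45) and GAR1 (0.47). It did not pass without WT replicate 2 (0.12, camera adjusted p = 0.0627). Elongation and termination factors had a median of 0.21 over 15 genes (camera adjusted p = 0.0261; adjusted p = 0.817 with an estimated correlation), with SUP45, the release factor eRF1, at 0.35. This call was lost without WT replicate 2 (0.16) and without mutant replicate 2 (0.15). Mitochondrial ribosomal proteins had a median of 0.04 over 71 genes (camera adjusted p = 0.539), which was -0.12 without WT replicate 1 and 0.17 without WT replicate 2.

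The lists of general stress and of cell wall genes were lower in mutant by camera with the preset correlation, while those of oxidative stress and chaperones did not pass. Of 31 general stress genes, the type activated by Msn2 and Msn4, 26 lay below 0, with a median of -0.38 (camera adjusted p = 9.4e-06; adjusted p = 0.817 with an estimated correlation). The median was -0.22 without WT replicate 1, -0.65 without mutant replicate 1 and -0.09 without mutant replicate 2, each past the camera threshold. The median deviation of these genes from the mean of all libraries was 0.29 and 0.07 in WT replicates 1 and 2. It was 0.02 and -0.41 in mutant replicates 1 and 2, so WT replicate 2 and mutant replicate 1 lay close together. PGM2 belongs to this list, as do OM45, an outer mitochondrial membrane protein (log2 fold change -0.67), and DCS2 (-1.37). Cell wall genes had 24 of 28 below 0 and a median of -0.50 (camera adjusted p = 9.4e-06; adjusted p = 0.817 with an estimated correlation), or -0.18 without WT replicate 1. CWP1, a mannoprotein, had 130 ± 8.22 CPM in WT and 82.7 ± 0.776 CPM in mutant (SD, n = 2 each). Of these 28 genes 19 encode a hydrophobic segment, a class that was raised in WT replicate 1. When only genes with no segment were tested, the cell wall median was -0.42 (camera adjusted p = 0.0343).

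The lists of the iron regulon, the zinc regulon and polyamine transport, which also holds kinases of that transport, were lower too. Leaving out WT replicate 1 moved the medians of polyamine transport and iron across 0, while that of zinc stayed below 0. All 13 measured genes of the list of polyamine transport and its kinases encode a hydrophobic segment as marked here. Their median was -0.41 (camera adjusted p = 0.0164, or 0.886 with an estimated correlation). Without WT replicate 1 the median was 0.05, on the other side of 0. DUR3, a urea and polyamine transporter, had 157 CPM in WT replicate 1 and 30.3, 39.8 and 41.8 CPM in the other libraries. AGP2, a plasma membrane regulator of transport, was lower in both mutant libraries (13.6 and 9.25 CPM) than in WT (22.8 and 18.5 CPM). The iron regulon had a median of -0.29 over 20 genes (camera adjusted p = 0.04999; adjusted p = 0.919 with an estimated correlation) and of 0.03 without WT replicate 1; the median of the edgeR fold changes was -0.56. The zinc regulon had a median of -0.31 over 14 genes (camera adjusted p = 0.0185; adjusted p = 0.817 with an estimated correlation) and of -0.23 without WT replicate 1. It lost its call without mutant replicate 1 (-0.28, camera adjusted p = 0.269). ZPS1, a zinc-regulated surface protein, had 2561 ± 167 CPM in WT and 1950 ± 47.2 CPM in mutant.

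Glycolysis and ethanol genes had a median of -0.17, with 16 of 22 below 0 (camera adjusted p = 0.04999; adjusted p = 0.817 with an estimated correlation). The median was -0.21 without WT replicate 1 (camera adjusted p = 0.00205) and the call was lost without any other single library. ADH1 had 5658 CPM in WT replicate 1, 2557 CPM in WT replicate 2 and 1339 and 1522 CPM in mutant. ADH2 had 444 ± 119 CPM in WT and 198 ± 31.6 CPM in mutant (SD, n = 2 each), and TDH1 966 ± 136 CPM and 591 ± 119 CPM. Genes of the TCA cycle and respiration had a median of 0.13 over 47 genes (camera adjusted p = 0.0261; adjusted p = 0.919 with an estimated correlation), which was -0.02 without WT replicate 1. The call was also lost without mutant replicate 1 (0.13, camera adjusted p = 0.209) and without mutant replicate 2 (0.12, camera adjusted p = 0.0884). Within that list COX7 and COX8 had log2 fold changes of 1.00 and 0.58, and ACO1, the aconitase, and CYB2 of -0.56 and -1.01. Hexose transport had a median of -0.35 (camera adjusted p = 0.248) and mitochondrially encoded genes of -0.47 over 4 genes (camera adjusted p = 0.824), or -0.71 by edgeR fold changes.

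The list of other amino acid synthesis was higher in mutant, with 33 of 42 genes above 0 and a median of 0.17 (camera adjusted p = 0.00106; adjusted p = 0.817 with an estimated correlation). It did not pass without WT replicate 2 (0.11, camera adjusted p = 0.184). PRO2 of proline synthesis had a log2 fold change of 0.41 and ARO2 of aromatic amino acid synthesis 0.40, while LYS20, a homocitrate synthase, had -0.47. Arginine synthesis did not pass with all libraries (median 0.15, camera adjusted p = 0.138) and did without WT replicate 1 (0.46, camera adjusted p = 1.7e-06). With an estimated correlation its adjusted p was 0.953 with all libraries and 0.837 without WT replicate 1. Genes of arginine catabolism and nitrogen catabolite repression had a median of -0.24 (camera adjusted p = 0.268), which passed at 0.16 without WT replicate 1 and at -0.60 without WT replicate 2. With an estimated correlation, a check added after the data were seen, 0 of the 34 lists passed without WT replicate 1 and 0 without WT replicate 2. Sulfur and methionine synthesis had a median of 0.07 (camera adjusted p = 0.288), purine synthesis and one-carbon metabolism of -0.09 (0.21) and pyrimidine synthesis of 0.03 (0.7). GCV1 and GCV2, subunits of glycine decarboxylase, had log2 fold changes of -0.99 and -0.63.

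Other lists did not pass with all 4 libraries. Their medians were 0.06 for chaperones and heat shock (camera adjusted p = 0.64), -0.01 for oxidative stress (0.819), -0.15 for the phosphate regulon (0.268), 0.10 for ergosterol synthesis (0.559), 0.04 for the proteasome (0.693), -0.18 for thiamine (0.924), 0.01 for histones (0.819) and 0.08 for cell cycle and daughter cell genes (0.559). Marker genes of the strain background, with a list median of 0.03 (0.789), included LEU2 at a log2 fold change of 0.62 and URA3 at -0.35. Both values rested largely on mutant replicate 2. LEU2 was at 0.29 without it, and URA3 had 27.6 and 19.2 CPM in mutant replicates 1 and 2, against 31.4 and 29.3 CPM in WT. HIS3, chosen after its values were seen, had 0 counts in each library, which allows up to 0.101 CPM in WT replicate 1 and 1.06 CPM in mutant replicate 2.

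Markers of type a cells were measured in every library and most markers of type alpha lay near 0. STE2, the receptor that type a cells carry, had 54.8 to 137 CPM, and MFA1, a pheromone precursor of type a, had 23.7 to 48.2 CPM. MF(ALPHA)1, the main pheromone gene of the opposite type, had 1 to 6 counts per library. STE3, another marker of type alpha, had 6 to 225 counts, or 2.12 to 7.58 CPM. The genes of the alpha locus at MAT, which has silent copies elsewhere, had 0 counts. The treatment of reads with several matches is not given, so the 0 counts at MAT do not tell the mating type. The list of type a markers had a median of -0.29 (camera adjusted p = 0.575), genes of haploid cells and pheromone response of 0.04 (0.788) and markers of meiosis and sporulation of 0.12 (0.559). Of 9 alpha markers 2 were measured, and the list was too short to test. MFA1 and MF(ALPHA)1 were chosen after their values were seen.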

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

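The alternatives in this section were chosen before the data were examined except sample quality weights, genes with no hydrophobic segment, thinning, and an estimated correlation without a WT library. The gene counts depended on which WT library was used. With 1 library left out, genes higher in mutant ranged from 0 to 228 and genes lower from 0 to 780, with 17 and 22 without WT replicate 1. DESeq2 called 4 lower and 0 higher, and every other setting called 0. OAZ1 stayed above 0 in each setting, from 0.36 in 1 thinning draw (median 0.69 over 20 further draws, 0.31 to 1.00) to 0.87 without WT replicate 1; leave-outs spanned 0.63 to 0.87, past the threshold at 0.63 without WT replicate 2. Leaving out either WT library removes by construction the difference between the WT libraries from the estimated spread.

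The 3 lists of cytosolic ribosomal proteins, general stress and cell wall genes kept their camera call in all 4 leave-outs. With an estimated correlation as well, 0 lists passed without WT replicate 1 (0.20, -0.22 and -0.18 for these 3, and 0.19 for elongation and termination factors) and 0 without WT replicate 2 (0.34, -0.48 and -0.79). Camera with an estimated correlation, and fry, ended all 11 calls with the medians as they were: 0.25 for cytosolic ribosomal proteins, 0.18 for ribosome biogenesis, 0.21 for elongation and termination factors, 0.17 for other amino acid synthesis, 0.13 for TCA cycle and respiration, -0.41 for polyamine transport, -0.38 for general stress, -0.50 for cell wall, -0.31 for zinc, -0.29 for iron and -0.17 for glycolysis and ethanol. These tests allow for genes that move together, which the preset correlation of 0.01 does to a small degree. With 4 libraries or fewer, camera with an estimated correlation can hardly pass any list, and fry was not checked on simulated lists. The lost calls therefore do not show that genes moving together account for the camera calls.

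Iron and glycolysis, which lay at the threshold, were lost with RLE scaling (-0.29 and -0.17), with no filter (-0.29 and -0.17) and without ribosomal protein genes (-0.28 and -0.16). Glycolysis was lost with upper-quartile scaling (-0.11) and iron with a mean count of at least 100 (-0.24). Among genes with no hydrophobic segment, the iron median reversed to 0.0256, and zinc (-0.0694), TCA cycle and respiration (0.0505) and elongation and termination factors (0.16) were no longer called. There fewer genes were tested; beyond that the cause was not tested.

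Over the leave-outs, list medians that changed their call ranged from -0.89 to 0.0472 for polyamine transport (reversed without WT replicate 1), from -0.60 to 0.16 for arginine catabolism (reversed without WT replicate 1), from -0.12 to 0.17 for mitochondrial ribosomal proteins (reversed without WT replicate 1), from -0.70 to 0.0332 for iron (above 0 without WT replicate 1), -0.54 to -0.23 for zinc, -0.21 to -0.0934 for glycolysis and ethanol, -0.02 to 0.25 for TCA cycle and respiration (below 0 without WT replicate 1), 0.11 to 0.23 for other amino acid synthesis, 0.12 to 0.28 for ribosome biogenesis and 0.15 to 0.22 for elongation and termination factors. Lists called only in some leave-outs ranged from 0.0672 to 0.37 for methionine salvage, 0.0268 to 0.0852 for sulfur and methionine synthesis, -0.0908 to 0.46 for arginine synthesis, -0.20 to -0.00508 for purine synthesis, -0.91 to -0.00362 for hexose transport, -1.25 to 0.29 for mitochondrially encoded genes, 0.0402 to 0.16 for ergosterol synthesis and -0.23 to 0.29 for meiosis and sporulation. The cause was not tested.

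The labels give both groups replicate numbers 1 and 2. Whether equal numbers mark a shared batch is not stated. The correlation of deviations between equal numbers was 0.080. With 2 libraries per group this is a single value, the same for both numbers, and it cannot exclude a shared batch. The replicate block called 0 genes, with 447 at an unadjusted p under 0.05, gave OAZ1 a log2 fold change of 0.72, and ended the calls of iron (-0.29) and glycolysis (-0.17).

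Of single named genes, 95 values passed the threshold under an alternative and not with all libraries, and 2090 stayed on their side. Values past no threshold were given no direction; 31 of 2203 named gene values under alternatives and 45 of 534 list tests had the other sign. The other splits of the 4 libraries into pairs gave 210 and 66 genes at an unadjusted p under 0.05, against 285 for the real one, and 3 splits are too few for a share under 0.05. OAZ1 had 49 counts in mutant replicate 2, so depth limits what its value there can show.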

Other observations

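The tests chosen only after the result was seen were those on membrane-bound mRNAs in WT replicate 1, on its displacement as a source of the list pattern, on growth state, and on counting error and overlapping genes for OAZ1. In addition, the tests of growth state and of membrane-bound mRNAs as the whole cause were revised after their values had been seen, the latter 2 times, and every version is given.

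Among the 24 genes called in both WT leave-outs, some lay outside the naming rule and were chosen after their values were seen. AZR1, a drug-efflux transporter of the plasma membrane, had 0.337 and 0 CPM in WT replicates 1 and 2 and 4.89 and 2.12 CPM in mutant replicates 1 and 2. FLO1, a flocculation protein with repeats shared with related genes, had 59.6 and 23.1 CPM in WT and 12.4 and 4.6 CPM in mutant. TIP1, a cell wall mannoprotein, had 66.5 and 78.2 CPM in WT and 44.3 and 33.6 CPM in mutant. RPL41A and RPL41B, which share most of their sequence, were at 32.5 and 25.1 CPM in mutant replicate 2 and at 129 and 98.8 CPM in mutant replicate 1, so they went against the ribosomal protein list mainly in 1 library. YGL088W had 1312 and 2190 CPM in WT and 3022 and 4531 CPM in mutant, and overlaps the small nucleolar RNA SNR10, so its counts are uncertain.

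WT replicate 1 lay apart from the other 3 libraries. Genes with a hydrophobic segment stood 0.443 higher on the log2 scale than other genes there (bootstrap interval over genes 0.403 to 0.508). The largest absolute difference in another library was 0.222. For those libraries the mean of the other 3 includes WT replicate 1, so part of that value follows from its displacement. More ribosomes on membrane-bound mRNAs in the lysate of WT replicate 1 is a candidate explanation. Depth is argued against, since the SD between the WT libraries after thinning was 0.535 and the largest SD among the other pairs 0.356. GC content and coding length removed 19.2% of the variance, the segment alone 21.6% and both 35.4%, which leaves a part for each open. The segment class, as marked here, is argued against as the whole cause, since among genes with no segment the SD against the same mutant library was larger for WT replicate 1 than for WT replicate 2 by at least 0.106 (0.0902 to 0.121), and by at least 0.0526 (0.0394 to 0.0657) with a median absolute deviation; earlier versions set the SD between the WT libraries, 0.349 (0.336 to 0.361), against the largest other pair, 0.334, and gave an excess of -0.00159 to 0.0311.

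Ribosomal protein genes were higher and general stress genes lower in mutant by camera with the preset correlation, though neither call was kept with an estimated correlation (adjusted p = 0.817) and 0 lists passed by fry. Displacement of WT replicate 1 as the whole source is argued against in these libraries. With WT replicate 2 alone and no hydrophobic segments the medians still lay 0.402 apart (0.275 to 0.467). Reads shared between paralogs are also argued against, since 42 ribosomal protein genes with little shared sequence had a median of 0.222 (0.186 to 0.318). Both intervals come from resampling genes, so they leave out the spread between libraries. The score of ribosomal protein minus stress deviations was -0.50 and -0.12 in WT and 0.05 and 0.62 in mutant, so mutant replicate 2 set much of the gap. Its gap between groups was 1.12 times the larger difference within a group, and 0.775 times in a first version that took differences of list medians. The growth state of single cultures may therefore account for the pattern and cannot be told apart from genotype with 2 libraries each. The score also rose in the order in which the library totals fell, and both mutant libraries were shallower than both WT libraries. The lists were not tested on thinned counts, so depth cannot be told apart from genotype for this pattern either.

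OAZ1 was higher in both mutant libraries. Counting error of independent reads is argued against, since the lower bound of the pooled mutant share was 1.31 times the upper bound of the pooled WT share, 20.1 CPM (17.6 to 23.0) against 12.3 CPM (11.2 to 13.4), although pooling leaves out the spread between libraries and the intervals of mutant replicate 2 and WT replicate 1 overlap. Overlap after thinning had also been set as a sign of counting error and occurred in the draw used and in 284 of 1000 further draws, but thinning discards counts and so widens the intervals whatever the cause. Reads from an overlapping or similar gene are argued against, with 0 overlapping genes and 0% of 28-mers shared. OAZ1 mRNA level rather than ribosomes past the frameshift site could give the same total and cannot be told apart from it, with 0 RNA-seq libraries analysed, and the removed frame change, a biological explanation, was not tested.

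Polyamines supply the modification of eIF5A, which helps ribosomes through proline runs, so constitutive antizyme might change counts on genes with such runs. The direction does not follow from this, since ribosomes held at a run would add to the count. The hypothesis was lower ribosome counts on the 449 genes with 3 prolines in a row, and it was not borne out: their median log2 fold change differed from that of 4761 others by -0.0285 (two-sided permutation test with 100000 resamples, p = 0.0586, Benjamini-Hochberg adjusted over 3 comparisons 0.0879), and by -0.0156 (permutation p = 0.253) against WT replicate 2 alone. Among genes with no hydrophobic segment the difference was -0.0407 (permutation p = 0.00733, adjusted 0.022), below the 0.1 set as the smallest difference of interest. Genes are not independent replicates, so these p-values describe the libraries. The counts are totals per coding sequence, so the test cannot show whether ribosomes were held at the runs themselves.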
